A study of Bos taurus with 20 samples.

How the data were processed

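Pituitary gene expression was measured on 20 single-colour Affymetrix bovine arrays, each from the whole gland of 1 steer that had grazed tall fescue carrying a fungal endophyte. The labels place the steers in 3 groups by the selenium they were given. ISe animals received inorganic selenium as sodium selenite (6 arrays), OSe animals received the selenium yeast product SEL-PLEX, an organic form (7 arrays), and MIX animals received equal parts of both (7 arrays). Per the labels' protocols, glands were taken at death and frozen, total RNA was extracted with TRIzol, and the fragmented product was labelled with biotin. Each array is labelled as a separate biological replicate. Scan dates and batches are not given in the sources used here.

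The submitters' processing notes name GCOS 1.2 and Partek without a role for either. Background correction, normalization and the summary of probes are not given in the sources used here. The authors' deposited table holds 26773 probes per array as log2 values, a unit read from the values themselves, which ran from 1.78 to 14.35 with a median between 6.60 and 6.64 in each array. The sorted values of any 2 arrays differed by at most 0.247, so the arrays had been brought to nearly the same distribution before deposit, and they were used here as deposited. Values near the top of the scale are compressed on such arrays, and differences in the most abundant transcripts are then understated. No background or detection value was used here, so no probe was called absent. Control probes were not marked and none was removed.

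Of the 26773 probes, 18550 carried 1 gene symbol in the platform annotation, 595 carried several and 7628 carried none. Only probes with 1 symbol were named. The gene identifiers of 17996 of them matched the reference gene table, and 0 symbols needed updating. The named probes covered 18087 symbols, of which 416 had more than 1 probe. In gene lists a gene was represented by its probe with the highest mean over the 20 arrays.

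Each probe was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3. A single fit held all 20 arrays with the group as the only term, which left 17 residual degrees of freedom, to which the moderation added 3.44. The contrasts read from it were: OSe minus ISe, MIX minus ISe, OSe minus MIX, and MIX minus the midpoint of ISe and OSe. A moderated F test covered any difference among the 3 groups. P-values were adjusted by Benjamini-Hochberg over all 26773 probes, with a threshold of 0.05. Errors of differences are standard errors of the fit, and group values are means ± SD over arrays. The number of arrays limits the precision: the median standard error of a log2 difference was 0.0913 for both contrasts against ISe and 0.0877 for OSe minus MIX.

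The comparisons, the 30 gene lists and the rule for naming genes were fixed before the data were examined. Lists were tested with camera in limma, which asks whether the members of a list are shifted relative to all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 30 lists and 3 contrasts. The same test was repeated with the correlation estimated from the data. The fry test of limma was run beside it, for genes moving on balance one way and for change in either direction. List members were also tested singly, adjusted over all probes and adjusted over the list alone. List scores are the mean over members of each gene's z score across the 20 arrays. An exact permutation test of these scores was chosen after the data had been seen. Its smallest possible p is 5.83e-04, so adjusted over 90 tests a single list could not reach 0.05 by itself.

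The naming rule takes, where fewer than 10 named genes pass the threshold in a contrast, the 20 named genes of smallest p, given as ranked and not as past the threshold. It adds all hormone genes and selenoproteins, and any list member that passes the adjustment over all probes or over its list alone, with the 4 of smallest p named where there are more. For lists called as a whole that have no such member, 2 members of small p are named, a choice made after their values were seen.

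The procedure was tested on simulated data with the real means and residual spreads, in which 50 probes were changed by each of 4 log2 sizes among 26773. For OSe minus ISe it recovered 42% of changes of 0.3, 68% of 0.5, 94% of 1 and 98% of 2, with 8 false calls. For MIX minus ISe the shares were 20%, 66%, 98% and 100%, with 10 false calls. For OSe minus MIX they were 24%, 68%, 98% and 100%, with 7 false calls. These simulated probes were independent of each other, which real genes are not. All 4 sizes were present together, and the large changes ease the Benjamini-Hochberg threshold for the small ones. The recovery of small changes is then overstated for data without large ones. A shift of 0.2 given to the oxidative phosphorylation list was estimated at 0.202, and 0 other lists were called.

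Alternatives covered quantile normalization, centring each array on its median, filters on dim and unnamed probes, the variance moderation, array weights, a block on the replicate number, a tissue score as covariate, fits on only the 2 groups compared, the mean of all probes of a gene, other thresholds, a split of the ISe arrays 3 and 3, and leaving out each array in turn. Fits without the 2 arrays of lowest weight and without the 3 arrays lowest on the first principal component were added after the data had been seen.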

Results

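Pituitary transcripts were compared among steers given selenite (ISe, 6 arrays), the organic form (OSe, 7 arrays) or the blend (MIX, 7 arrays). The 20 arrays were alike in overall profile, with pairwise correlations across probes between 0.98 and 0.9903 and 0 identical pairs. The first principal component took 11.4% of the variance and the second 10.5%. On the first, MIX replicates 5, 6 and 7 lay farthest to one side, at -32.9, -19.3 and -13.6, and ISe replicate 5 farthest to the other, at 24.4. On the second, ISe replicate 1 lay at 5.18, above 1 of the 7 OSe arrays, whereas the other ISe arrays lay between -1.61 and -32.7. Hormone genes gave some of the brightest probes. GH1 (growth hormone), LHB (the beta subunit of luteinizing hormone) and CGA (the alpha subunit shared by the glycoprotein hormones) had means of 13.74, 13.83 and 13.71 in ISe, against a highest value of 14.35 on any array.

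**Figure D1:**
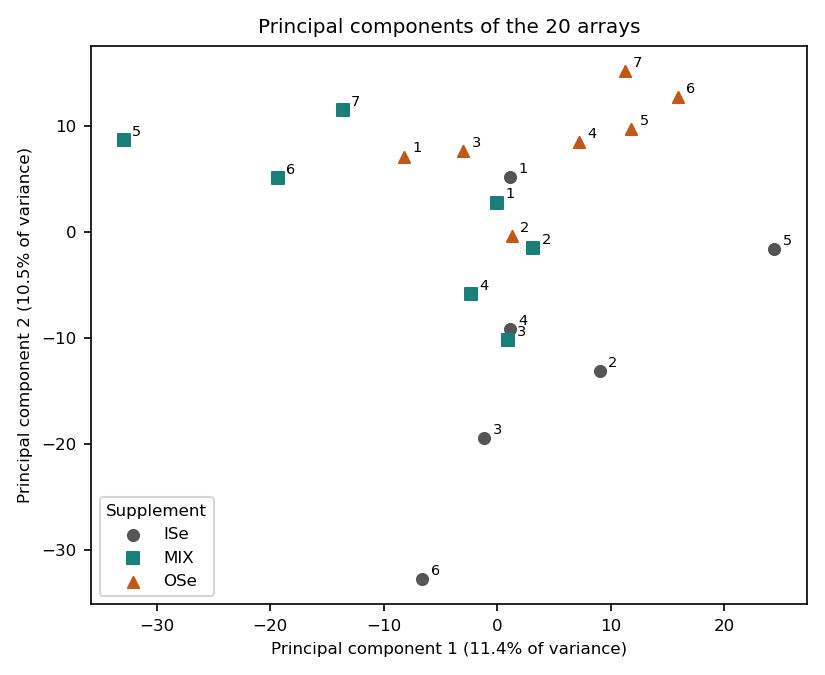
Each point is 1 array, placed by its first and second principal components over all probes and marked by supplement, with its replicate number beside it. MIX replicates 5, 6 and 7 lie to the left, and ISe replicate 1 lies at 5.18 on the vertical axis, above the other ISe arrays.

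The first question was whether the form of selenium altered pituitary transcripts at all. In limma's test of any difference among ISe, OSe and MIX, 0 probes passed the adjusted threshold, and the smallest adjusted p was 0.141. At an unadjusted p under 0.05 there were 3674 probes, and 1055 had an unadjusted p under 0.01, where 268 are expected by chance. The count past the adjusted threshold was 6 without ISe replicate 1, 2 without ISe replicate 5, 1 without MIX replicate 5, 1 without the 2 arrays of lowest weight and 2 without MIX replicates 5, 6 and 7. The count at an unadjusted p under 0.01 was 653 with the posterior lobe score as a covariate, 606 with the intermediate lobe score and 675 without the 2 arrays of lowest weight.

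Steers given organic selenium had more transcript of 2 hormone genes than steers given selenite. PRL, which encodes prolactin, was 1.18-fold higher in OSe, at 13.62 ± 0.083 against 13.39 ± 0.20 in ISe (SD, n = 7 and 6), and 7 of 7 OSe arrays lay above the ISe mean. POMC, the precursor of corticotropin and melanocyte-stimulating hormone, was 1.23-fold higher, at 13.43 ± 0.15 against 13.13 ± 0.22, with 6 of 7 OSe arrays above the ISe mean. DRD2, the dopamine receptor through which dopamine and ergot alkaloids restrain prolactin, was 1.27-fold higher. PRL and POMC passed when adjusted over the list alone among 7 hormone genes, both at adjusted p = 0.0365, and neither passed over all probes (adjusted p = 0.212 and 0.237). The other hormone genes passed neither adjustment. FSHB differed by -0.20 ± 0.089 (log2 difference and its standard error), TSHB by 0.24 ± 0.14, and GH1, CGA and LHB by 0.029, -0.017 and -0.016, the last 3 close to the top of the scale. PRL and POMC were nearly as bright, where such arrays compress differences. The hormone genes as a list had adjusted p = 0.433. The count of 2 hormone genes became 0 with quantile normalization, with either tissue score as a covariate and without the 2 arrays of lowest weight. It became 0 without OSe replicate 1, 3, 5, 6 or 7 or ISe replicate 2, 3 or 6, 1 without OSe replicate 2 or ISe replicate 5, and 3 without ISe replicate 1.

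Genes that process and store peptide hormones were higher in OSe than in ISe as a group. Of 17 members, 12 lay above 0, and 6 passed adjusted over the list alone. VGF, a granin-like secretory peptide, was higher by 0.57 ± 0.13, the granule protein CHGB by 0.22 ± 0.066, the prohormone convertase PCSK1 by 0.53 ± 0.19, and the amidating enzyme PAM by 0.36 ± 0.14. The list rose with camera (adjusted p = 0.00278, and adjusted p = 0.487 with an estimated correlation). Markers of intermediate lobe melanotrophs, the POMC cells that dopamine inhibits, also rose, with 7 of 7 OSe arrays above the ISe mean of their score. Of the 7 measured members 6 lay above 0, and DRD2 (0.35 ± 0.11), POMC (0.30 ± 0.11), OACYL (0.45 ± 0.17) and PCSK2 (0.41 ± 0.16) each passed adjusted over the list alone at adjusted p = 0.0286. Camera gave this list adjusted p = 0.00538, and adjusted p = 0.467 with an estimated correlation. PCSK2 is a member of both lists. POMC and TBX19 are also in the corticotroph list and DRD2 in the lactotroph list, so these members are not specific to the intermediate lobe. PAX7, also listed for melanotrophs, was not measured. With the score of the intermediate lobe genes other than POMC as a covariate, the prohormone list no longer passed (adjusted p = 0.365, in a range of 4.03e-04 to 0.365 over its alternatives with the preset correlation).

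Posterior lobe markers fell in OSe, with 9 of 10 members below 0 and 7 of 7 OSe arrays below the ISe mean (adjusted p = 0.0106, and adjusted p = 0.467 with an estimated correlation). No member passed adjusted over the list alone. GFAP, the filament of glia-like pituicytes, differed by -0.56 ± 0.23 and the vasopressin gene AVP by -0.23 ± 0.10. The list was not past the threshold among probes above the median probe (adjusted p = 0.359, in a range of 0.00458 to 0.359). Immune cell markers rose, with 13 of 14 members above 0 (adjusted p = 0.00486, and adjusted p = 0.524 with an estimated correlation). Among them the macrophage receptor CSF1R differed by 0.27 ± 0.098 and the complement gene C1QA by 0.27 ± 0.10, neither past the threshold adjusted over the list alone. The lactotroph, corticotroph and folliculostellate lists had adjusted p of 0.665, 0.799 and 0.205 in camera. Adjusted over the list alone, DRD2 and PRL passed among lactotroph genes, POMC and PCSK1 among corticotroph genes, and CXADR (-0.18 ± 0.059) and GFRA3 (-0.37 ± 0.13) among folliculostellate and stem cell genes.

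**Figure D2:**
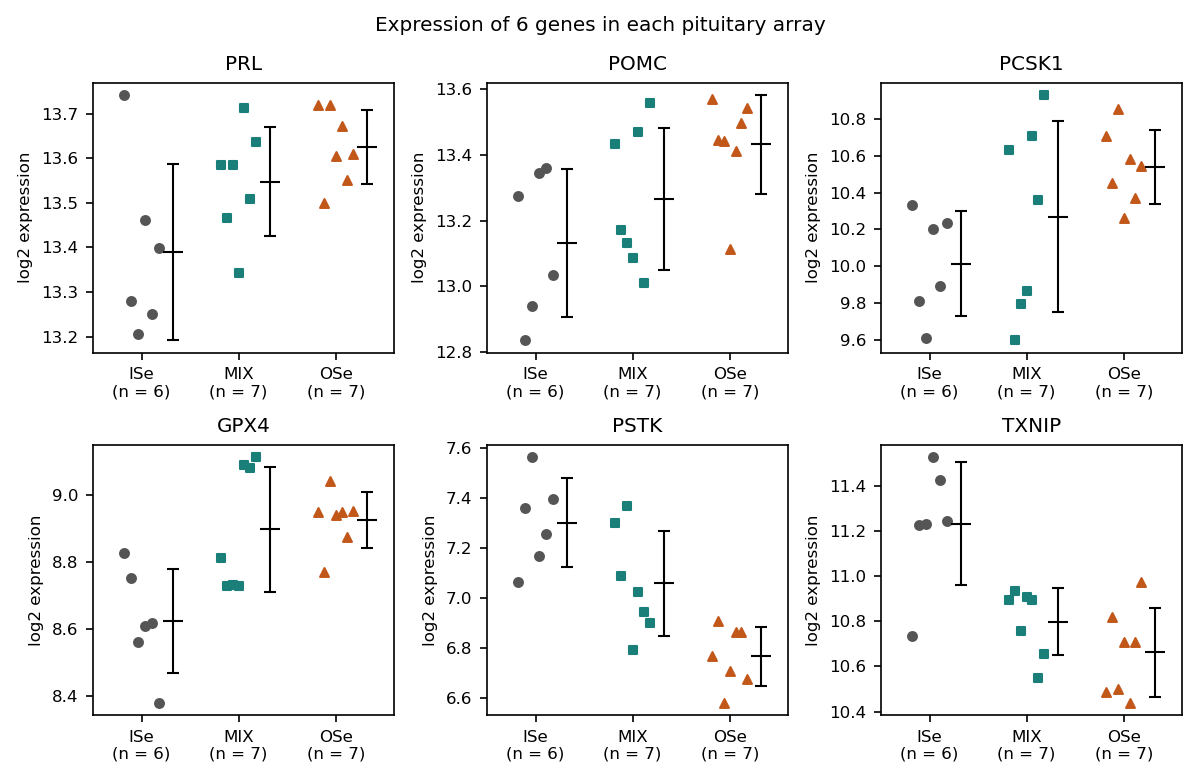
Log2 expression of PRL, POMC, PCSK1, GPX4, PSTK and TXNIP is plotted for each array, with replicates in order from left to right within a group and the group mean ± SD as a bar beside them. ISe replicate 1, the first ISe point, had the highest PRL and the lowest TXNIP of its group, at 13.74 and 10.73.

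In selenium biology, an enzyme of selenocysteine synthesis and a lipid peroxidase stood out between OSe and ISe. PSTK, the kinase that phosphorylates seryl-tRNA on the way to selenocysteine, was 1.45-fold lower in OSe (-0.53 ± 0.094), and 7 of 7 OSe arrays lay below the ISe mean. It passed adjusted over the list alone among 14 selenium handling genes (adjusted p = 1.91e-04) and had adjusted p = 0.0592 over all probes. GPX4, the peroxidase that reduces lipid hydroperoxides, was 1.23-fold higher (0.30 ± 0.082), with adjusted p = 0.0381 adjusted over the list alone and 0.14 over all probes. It was the 1 selenoprotein of 24 to pass, and 16 of the 24 lay above 0. GPX3 differed by 0.65 ± 0.20, MSRB1 by 0.25 ± 0.091, SELENOM by 0.33 ± 0.13, SELENOO by 0.21 ± 0.084 and SEPHS2 by -0.18 ± 0.070, with adjusted p from 0.0528 to 0.0828 adjusted over the list alone. The other 18 (SELENOK, SELENON, SELENOF, SELENOH, SELENOI, SELENOP, SELENOS, SELENOT, SELENOV, SELENOW, GPX1, GPX2, DIO1, DIO2, DIO3, TXNRD1, TXNRD2 and TXNRD3) differed by -0.17 to 0.18. The selenoprotein list as a whole had adjusted p = 0.205 and the selenium handling list adjusted p = 0.665. The count of 1 selenoprotein changed in 15 of the 20 fits that left out 1 array, from 0 without OSe replicate 1, for example, to 6 without ISe replicate 1. It became 0 with a block on the replicate number, with either tissue score as a covariate and without the 2 arrays of lowest weight, 2 with array weights, only named probes or only the 2 groups compared and without MIX replicates 5, 6 and 7, and 6 with only probes above the median probe.

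Among antioxidant genes, the thioredoxin inhibitor TXNIP was 1.48-fold lower in OSe than in ISe (-0.57 ± 0.11), and the heme oxygenase HMOX1 was 1.24-fold higher (0.31 ± 0.082). Both passed adjusted over the list alone (adjusted p = 0.00132 and 0.0143), while the antioxidant list as a whole had adjusted p = 0.284 in camera.

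Genes of mitochondrial respiration, cytosolic ribosomes and endoplasmic reticulum stress were higher in OSe than in ISe, and genes that glucocorticoids induce were lower. Oxidative phosphorylation rose, with 56 of 71 members above 0 and a median log2 difference of 0.089 (adjusted p = 1.45e-05, and adjusted p = 0.487 with an estimated correlation). COX7A2 (0.31 ± 0.070), NDUFAB1 (0.28 ± 0.065) and ATP5MC1 (0.33 ± 0.089) passed adjusted over the list alone. Cytosolic ribosomal proteins, of which 38 of the 78 listed were measured here, rose as a list, with 33 of 38 measured members above 0 (adjusted p = 6.61e-05, and adjusted p = 0.635 with an estimated correlation). None passed singly, and RPLP0 differed by 0.22 ± 0.076 and RPL38 by 0.31 ± 0.11. The list of endoplasmic reticulum (ER) stress genes also rose, with 18 of 22 members above 0 (adjusted p = 1.07e-04, and adjusted p = 0.487 with an estimated correlation), with the asparagine synthetase ASNS (0.28 ± 0.053), the chaperone HYOU1 (0.29 ± 0.085) and the secreted factor MANF (0.19 ± 0.061) past the threshold adjusted over the list alone. Glucocorticoid-responsive genes fell as a list, with 10 of 11 members below 0 (adjusted p = 2.42e-05, and adjusted p = 0.487 with an estimated correlation). In this list 5 passed adjusted over the list alone, among them ERRFI1 (-0.48 ± 0.10), NFKBIA (-0.53 ± 0.13), CEBPD (-0.38 ± 0.11) and KLF9 (-0.24 ± 0.088). The proteasome list did not pass (adjusted p = 0.665), although its member PSMD8 (0.29 ± 0.072) did adjusted over the list alone. Heat shock proteins did not pass as a list either (adjusted p = 0.64), with 5 of 12 measured members above 0 and 7 below.

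**Figure D3:**
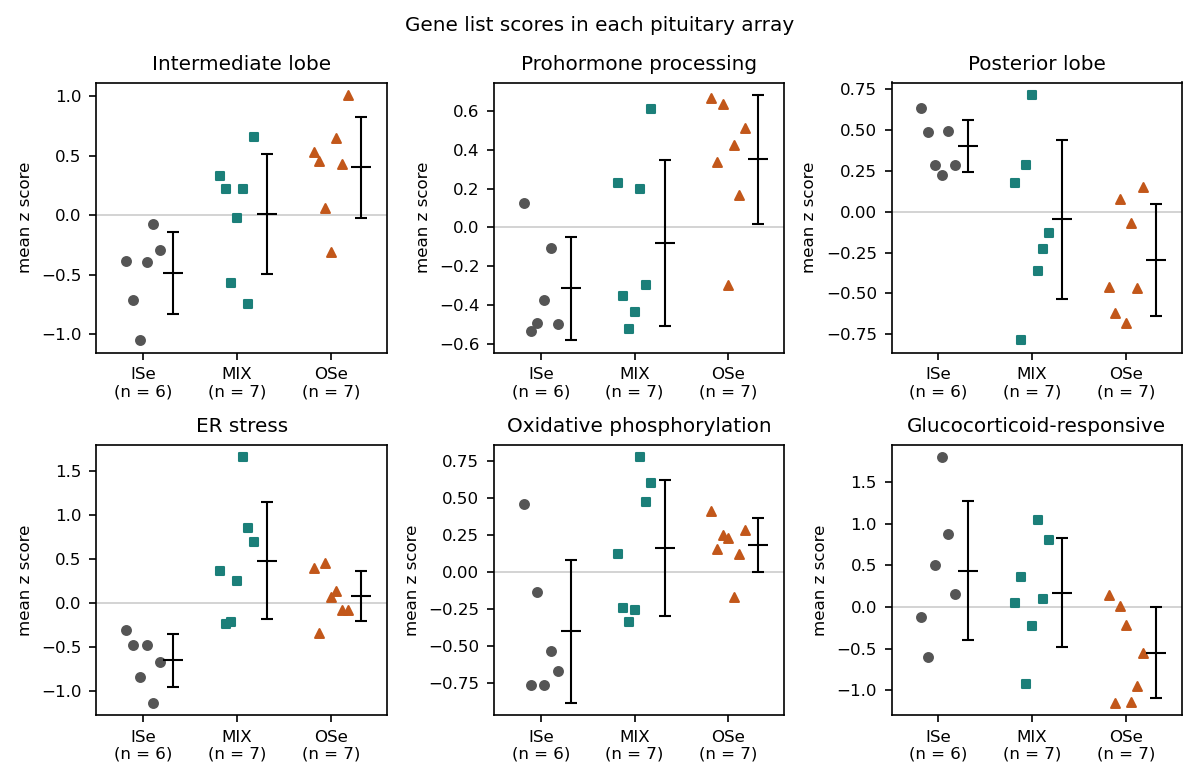
The mean z score of 6 gene lists is plotted for each array, with replicates in order from left to right within a group and the group mean ± SD as a bar beside them. MIX replicates 5, 6 and 7, the last 3 MIX points, have the highest ER stress scores (1.65, 0.851 and 0.691), and all ISe arrays lie below 0 for that list.

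Ranked by p, and not past the threshold, the genes that differed most clearly between OSe and ISe were ZDBF2 (1.93-fold lower in OSe, -0.95 ± 0.15), the axonemal dynein gene DNAI3 (-0.40 ± 0.065), and the circadian repressor BHLHE40 (1.52-fold higher, 0.60 ± 0.10). For all 3 the OSe and ISe arrays did not overlap. The other lower genes among the first 20 were RASGEF1B, GCNT1, PSTK, USP53, MIR1301, RUBCNL, FAM13C, VCPKMT, TIPARP, THSD7B, CFAP43, TXNIP and THAP1, at -0.33 to -0.74. The other higher genes were LYPLA2, IFI27L2, ABHD11 and ASNS, at 0.28 to 0.44. Adjusted p lay between 0.0534 and 0.0609 for all 20. BHLHE40 passed among the circadian clock genes adjusted over the list alone (adjusted p = 9.19e-05), and that list had adjusted p = 0.465. By limma's test 0 probes passed the adjusted threshold, 3485 had an unadjusted p under 0.05, and 1132 had an unadjusted p under 0.01 (520 higher and 612 lower in OSe), a count that was 748 without ISe replicate 6 and 1678 without ISe replicate 1. With the posterior lobe score as a covariate it was 584, and with the intermediate lobe score 475.

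The count of 0 lay close to the threshold and depended on the processing and on ISe replicate 1. With array weights 32 probes passed, with a trended and robust eBayes 53, with only named probes 38, with only probes above the median probe 105, with quantile normalization 11 and with the posterior lobe score as a covariate 9. Without ISe replicate 1, 241 probes passed (110 higher and 131 lower in OSe), among them all 20 ranked genes, and PRL (adjusted p = 0.0379 over all probes), DRD2 (0.0299), TXNIP (0.00553) and PSTK (0.0161) were past the threshold. ISe replicate 1 lay farther toward OSe than any other ISe array, so leaving it out tends to widen the difference. The 20 genes were ranked on the same arrays, so these calls add no support. Between 2 and 12 probes passed without ISe replicate 2 or 5, OSe replicate 2 or 3, or MIX replicate 1, 4, 5 or 7.

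In steers given the blend, the clearest difference from selenite by camera and fry was in the genes of ER stress and protein folding. Of 22 measured members 21 lay above 0 in MIX, with a median log2 difference of 0.15, and 9 passed adjusted over the list alone. HERPUD1, a component of ER-associated degradation, was 1.19-fold higher (0.25 ± 0.060), ASNS 1.15-fold (0.20 ± 0.053), the transcription factor XBP1 1.25-fold (0.32 ± 0.086) and the stress-induced factor DDIT3 1.26-fold (0.33 ± 0.089). The list rose with camera (adjusted p = 1.19e-09, and adjusted p = 0.467 with an estimated correlation). It was the 1 list and contrast of 90 past the threshold in fry's test of movement one way (adjusted p = 0.0228). The mean score was 0.479 ± 0.66 in MIX and -0.65 ± 0.30 in ISe (SD, n = 7 and 6, exact permutation p = 0.00233, adjusted 0.0524 over 90 such tests), and the arrays of the 2 groups did not overlap. Without MIX replicates 5, 6 and 7 the difference in score was 0.69 in place of 1.13, with a mean of 0.0399 ± 0.311 in the other 4 MIX arrays, and the list still passed (camera adjusted p = 2.51e-05, the highest of a range of 1.93e-11 to 2.51e-05).

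Genes of protein turnover and respiration were also higher in MIX than in ISe. Proteasome subunits rose as a list, with 26 of 30 members above 0 (adjusted p = 1.67e-05, and adjusted p = 0.487 with an estimated correlation), with PSMC5 at 0.17 ± 0.061 and PSMB4 at 0.21 ± 0.076. Oxidative phosphorylation rose as a list, with 58 of 71 above 0 (adjusted p = 1.45e-05, and adjusted p = 0.487 with an estimated correlation), with NDUFV1 at 0.20 ± 0.062 and ATP5MC1 at 0.29 ± 0.089. None of these 4 genes passed adjusted over its list alone. Heat shock proteins rose as a list, with 9 of 12 above 0 (adjusted p = 0.0306, and adjusted p = 0.543 with an estimated correlation), with HSPH1 (0.28 ± 0.084) and the mitochondrial cochaperone HSPE1 (0.21 ± 0.073) past the threshold adjusted over the list alone. The heat shock call was lost, at adjusted p of 0.0692 to 0.0976, without MIX replicate 5, 6 or 7 or ISe replicate 2, 5 or 6. It was also lost with quantile normalization (0.0525), a block on the replicate number (0.0547), array weights (0.0838), only probes above the median probe (0.115), the posterior lobe score as a covariate (0.458) and without the 2 arrays of lowest weight (0.203). These differences lay in part with 3 arrays. The proteasome scores of MIX replicates 5, 6 and 7 were 1.33, 1.09 and 0.763, and those of the other MIX arrays lay between -0.117 and 0.215. Without these 3 arrays the proteasome list (adjusted p = 0.126, in a range of 2.43e-06 to 0.126), the oxidative phosphorylation list (0.126, in a range of 2.2e-07 to 0.126) and the heat shock list (0.76, in a range of 0.00578 to 0.76) did not pass.

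Selenoproteins rose as a list in MIX against ISe, with 19 of 24 members above 0 (adjusted p = 0.00523, and adjusted p = 0.487 with an estimated correlation). Past the threshold adjusted over the list alone were 4 of them: the methionine sulfoxide reductase MSRB1 (0.30 ± 0.091), GPX4 (0.27 ± 0.082), SELENON (0.18 ± 0.060) and the cytosolic thioredoxin reductase TXNRD1 (0.17 ± 0.056). The other 20 differed by -0.25 (DIO3) to 0.55 (GPX3). Without MIX replicates 5, 6 and 7 the list did not pass (adjusted p = 0.273, in a range of 0.00124 to 0.273), and the count of 4 became 0. GPX4 stood at 9.08 to 9.11 in these 3 arrays and at 8.73 to 8.81 in the other MIX arrays. The count also became 0 with quantile normalization, array weights, a block on the replicate number, either tissue score as a covariate or only the 2 groups compared, and without the 2 arrays of lowest weight. It was 0 without MIX replicate 5, 6 or 7, OSe replicate 4 or 6, or ISe replicate 2, 3, 5 or 6, and 6 without MIX replicate 3 or ISe replicate 1.

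Among antioxidant genes, SRXN1, which repairs oxidized peroxiredoxins, was 1.51-fold higher in MIX than in ISe (0.60 ± 0.14) and TXNIP was 1.35-fold lower (-0.43 ± 0.11). HMOX1 (0.27 ± 0.082) and the pentose phosphate enzyme TKT (0.22 ± 0.071) were higher. All 4 passed adjusted over the list alone, at adjusted p of 0.0115 to 0.0406, and the list as a whole had adjusted p = 0.19. SRXN1 stood at 7.81 to 8.12 in MIX replicates 5, 6 and 7 and at 7.01 to 7.37 in the other MIX arrays. The selenium handling list had adjusted p = 0.641. PSTK had means of 7.30 ± 0.18 in ISe, 7.06 ± 0.21 in MIX and 6.76 ± 0.12 in OSe.

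Immune cell markers rose in MIX against ISe, with 12 of 14 members above 0 (adjusted p = 0.023, and adjusted p = 0.635 with an estimated correlation), and the scavenger receptor gene CD163 (0.43 ± 0.13) passed adjusted over the list alone. This call was lost without MIX replicate 1 (adjusted p = 0.106) or 3 (0.114) or ISe replicate 1 (0.0767), 3 (0.052) or 6 (0.102), with array weights (0.103), with only probes above the median probe (0.0734) and without the 2 arrays of lowest weight (0.164), in a range of 0.0040 to 0.164. Posterior lobe markers, with 8 of 10 members below 0, and intermediate lobe markers, with 7 of 7 above 0, moved the same way as in OSe. Neither list passed in camera (adjusted p = 0.119 and 0.197). No hormone gene passed adjusted over the list alone. PRL differed by 0.16 ± 0.078, POMC by 0.13 ± 0.11, TSHB by 0.21 ± 0.14, FSHB by -0.12 ± 0.089, and GH1, LHB and CGA by 0.010, 0.0093 and -0.0032. Without ISe replicate 1, 1 hormone gene did. Among clock genes BHLHE40 (1.43-fold higher, 0.52 ± 0.10), CRY1 (0.30 ± 0.086) and NR1D2 (-0.24 ± 0.081) passed adjusted over the list alone, with adjusted p = 0.284 for the list in camera. By the exact permutation test, chosen after the data had been seen, the clock score had the smallest p of 90 (p = 5.83e-04, adjusted 0.0524), and its MIX and ISe arrays did not overlap. The hemoglobin gene HBA was lower (-0.27 ± 0.079) and passed among the blood genes, whose list had adjusted p = 0.119. Its probe was dim, at 4.765 to 5.339 in the OSe arrays, below the median of each array.

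Ranked by p, and not past the threshold, MIX and ISe differed most clearly in the growth factor gene TGFB1 (1.46-fold higher, 0.55 ± 0.10), IFI27L2 (0.42 ± 0.082), BHLHE40, EMC8 (0.34 ± 0.066) and the collagen chaperone SERPINH1 (0.41 ± 0.080). POLR2D, SLC35C1, SEC14L2, SFXN3, XPNPEP1, ARID3A, PICK1, MTHFD1L, FAIM2, GNL1 and TXNDC5 were higher by 0.31 to 0.51. The 4 lower genes were MATCAP2 (-0.30), the chemokine CCL20 (-0.42), the myelin gene PMP22 (-0.39) and DNAI3 (-0.29). Adjusted p lay between 0.181 and 0.25 for all 20. By limma's test 0 probes passed the adjusted threshold (1 without MIX replicate 5, ISe replicate 5, the 2 arrays of lowest weight or MIX replicates 5, 6 and 7, and 2 with the intermediate lobe score as a covariate), 3070 had an unadjusted p under 0.05, and 848 had an unadjusted p under 0.01 (525 higher and 323 lower in MIX). The last count was 1324 without ISe replicate 1, 531 without MIX replicate 5, 490 with the posterior lobe score as a covariate, 461 without the 2 arrays of lowest weight and 236 without MIX replicates 5, 6 and 7. By chance 268 are expected, so no excess was left without MIX replicates 5, 6 and 7, in a fit with fewer arrays.

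Between the organic form and the blend, chaperone and proteasome genes were lower in OSe, and so were glucocorticoid-responsive genes. All 12 measured heat shock proteins lay below 0 (adjusted p = 4.69e-04, and adjusted p = 0.487 with an estimated correlation), and the cochaperone DNAJB1 (1.25-fold lower, -0.33 ± 0.084), HSPH1 (-0.24 ± 0.081) and HSPA8 (-0.14 ± 0.049) passed adjusted over the list alone. Proteasome genes fell as a list, with 25 of 30 members below 0 (adjusted p = 7.45e-05, and adjusted p = 0.487 with an estimated correlation), with PSMB2 at -0.16 ± 0.053 and PSMA1 at -0.15 ± 0.056. Glucocorticoid-responsive genes fell as a list, with 10 of 11 below 0 (adjusted p = 4.35e-04, and adjusted p = 0.524 with an estimated correlation), with FKBP5, a cochaperone of the glucocorticoid receptor (-0.41 ± 0.14), and KLF9 (-0.27 ± 0.085) past the threshold adjusted over the list alone. Without MIX replicates 5, 6 and 7 the heat shock list (adjusted p = 0.312, in a range of 4.82e-05 to 0.312), the proteasome list (0.511, in a range of 7.27e-06 to 0.511) and the glucocorticoid list (0.166, in a range of 1.73e-05 to 0.166) did not pass.

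Ribosomal proteins rose as a list in OSe against MIX, with 29 of 38 members above 0 (adjusted p = 0.00415, and adjusted p = 0.769 with an estimated correlation), with RPL23 at 0.10 ± 0.046 and RPL24 at 0.15 ± 0.068. Prohormone processing genes rose as a list, with 13 of 17 above 0 (adjusted p = 0.0251, and adjusted p = 0.487 with an estimated correlation), with VGF at 0.34 ± 0.12 and CPE at 0.095 ± 0.039. None of these 4 genes passed adjusted over its list alone. The unadjusted exact permutation p of the list score was 0.159 for ribosomal proteins and 0.0589 for prohormone processing. The ribosomal call was lost without OSe replicate 4 (adjusted p = 0.0599, in a range of 7.45e-06 to 0.0599). The prohormone call was lost without MIX replicate 2 (0.0736), 3 (0.114) or 4 (0.079) or OSe replicate 1 (0.107) or 3 (0.0742) and with the intermediate lobe score as a covariate (0.209), in a range of 7.77e-04 to 0.209.

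The cytosolic thioredoxin reductase was the 1 selenoprotein that differed between OSe and MIX adjusted over the list alone. TXNRD1 was 1.16-fold lower in OSe (-0.22 ± 0.054, adjusted p = 0.0158), at 8.96 ± 0.067 against 9.17 ± 0.12 in MIX. The other 23 differed by -0.20 (SELENOI) to 0.17 (DIO3), and the list had adjusted p = 0.309. The count of 1 became 0 without MIX replicates 5, 6 and 7, without the 2 arrays of lowest weight, with a block on the replicate number and with the intermediate lobe score as a covariate. In selenium handling, CBS, a transsulfuration enzyme, was higher (0.25 ± 0.070) and PSTK lower (-0.29 ± 0.091) in OSe, both past the threshold adjusted over the list alone, and the list had adjusted p = 0.809. HBA, at the same dim probe, was higher (0.25 ± 0.076) and passed among the blood genes, whose list had adjusted p = 0.205. No hormone gene passed: POMC differed by 0.17 ± 0.10, PRL by 0.077 ± 0.075, FSHB by -0.083 ± 0.085, TSHB by 0.029 ± 0.13, and LHB, GH1 and CGA by -0.026, 0.019 and -0.014. The ER stress list had adjusted p = 0.0534, with 15 of 22 members below 0. It passed without MIX replicate 2, 3 or 4 or OSe replicate 1 or 3 (adjusted p = 0.00958 to 0.0301), with each array centred on its median (0.0481), without variance moderation (0.033) and with a trended and robust eBayes (0.0256), and without MIX replicates 5, 6 and 7 its direction reversed (adjusted p = 0.777).

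Ranked by p, and not past the threshold, the genes lower in OSe than in MIX were led by the sodium-proton exchanger SLC9A2 (-0.45 ± 0.084) and the retinol acyltransferase LRAT (-0.41 ± 0.080). ZDBF2 (1.61-fold lower, -0.69 ± 0.14) was among them, with SPIRE1, MIR1301, ARF6, LAP3, PRTG, OSGEPL1, UBE3C, ZNF79, NUP50 and MIR2372 at -0.20 to -0.46. MIS18A, EFNB3, SMIM10, NPAS1, NLRC3, TCRA and SLC45A4 were higher by 0.21 to 0.68. All 20 had adjusted p = 0.288. The probes of ARF6 and TCRA disagreed. ARF6 was -0.28 at its brighter probe and 0.43 at the other, and the 11 probes annotated to TCRA went both ways, with the ranked one not the brightest. By limma's test 0 probes passed the adjusted threshold (1 without variance moderation), 2682 had an unadjusted p under 0.05, and 734 had an unadjusted p under 0.01 (363 higher and 371 lower in OSe), a count that was 417 without MIX replicates 5, 6 and 7 and 481 among probes above the median probe.

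The blend was also set against the midpoint of ISe and OSe, which equal contributions of both forms would give. By limma's test 0 probes passed the adjusted threshold (smallest adjusted p = 0.366; 1 probe passed without MIX replicate 5 or without the 2 arrays of lowest weight), 2608 had an unadjusted p under 0.05, and 637 had an unadjusted p under 0.01 (331 higher and 306 lower in MIX than the midpoint). The last count was 377 without MIX replicate 5, 225 without MIX replicates 5, 6 and 7 and 369 among probes above the median probe. Over all probes 268 are expected by chance, so no excess was left without MIX replicates 5, 6 and 7.

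The 2 comparisons with selenite shared genes such as BHLHE40, DNAI3, IFI27L2, TXNIP, ASNS and GPX4, which lay on the same side in both. At an unadjusted p under 0.01, 156 probes were higher in both and 94 lower in both, where independent lists of those sizes would share 10.2 and 7.38, and 0 lay on opposite sides. Both comparisons use the same 6 ISe arrays, which alone makes them alike. Log2 differences correlated at 0.58 across probes, which are not independent replicates (0.655 without ISe replicate 1), against 0.534 (0.32 to 0.661 over 100 draws) for simulated unchanged groups. The covariance was 0.0131 against a simulated mean of 0.00884 (0.00484 to 0.0135). With the ISe arrays split 3 and 3, so that the comparisons shared no array, the mean correlation over 10 splits was 0.141 (-0.00872 to 0.243) and the mean covariance 0.00426.

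Several cell types and pathways showed no shift past the threshold in any of the 3 contrasts. The smallest adjusted p over the 3 contrasts was 0.741 for somatotroph genes, 0.665 for gonadotroph genes, 0.448 for thyrotroph genes, 0.284 for myelin and oligodendrocyte genes, 0.77 for endothelial genes and 0.19 for fibroblast and mural cell genes. It was 0.309 for dopamine, adrenergic and serotonin signalling, 0.695 for immediate early genes, 0.644 for the cell cycle, 0.352 for interferon-stimulated genes and 0.264 for cholesterol synthesis. The median and the camera direction differed in sign for endothelial and interferon-stimulated genes in OSe against ISe, somatotroph genes in MIX against ISe, and fibroblast and selenium handling genes in OSe against MIX. For somatotroph genes in OSe against ISe the mean was below 0 while the median and camera were above. Fry's test of change in either direction passed, beyond lists called by camera in the same contrast, for antioxidant genes in OSe and MIX against ISe (adjusted p = 3.45e-04 and 0.00858), for selenium handling genes in OSe against ISe and against MIX (0.0125 and 0.0146), and for clock genes in OSe against ISe (0.0174). Camera called 19 of the 90 list tests, and 0 held with an estimated correlation. For several called lists the unadjusted exact permutation p of the score was 0.05 or more. It was 0.0699 (immune) and 0.0775 (ribosomal) in OSe against ISe. In MIX against ISe it was 0.0577 (oxidative phosphorylation), 0.0787 (heat shock) and 0.0833 (immune). In OSe against MIX it was 0.0507 (glucocorticoid-responsive), 0.0589 (prohormone) and 0.159 (ribosomal). For the other called lists it was 0.00175 to 0.0402. Splits of the arrays into random groups of the same sizes called a median of 4 lists in each contrast, against 8 for OSe against ISe, 6 for MIX against ISe and 5 for OSe against MIX.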

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

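The tests weighed in this part, and the counts over other splits of the arrays, were written down only after the results were seen. In 21 of 468 groups of values 1 array stood apart, where chance gives about 1 in 20, or 23. The highest or lowest array was far from the next for RASGEF1B in ISe replicate 1 (8.739), SFXN3 in ISe replicate 1 (7.209), LHB in ISe replicate 3 (13.76), TSHB in ISe replicate 5 (9.9), and SERPINH1 (7.74), FAIM2 (8.866) and SELENOH (5.546) in ISe replicate 6. In OSe it was GCNT1 in replicate 1 (7.169), HBA in replicate 3 (5.339), POMC (13.12) and OACYL (10.22) in replicate 4, TIPARP (7.878), DIO2 (9.152) and SELENOT (10.45) in replicate 5, and FAM13C in replicate 6 (8.208). In MIX it was CEBPD in replicate 3 (8.791), and FAM13C (7.984) and GH1 (13.84) in replicate 7. The endothelial score of ISe replicate 4 (0.6892), the interferon score of OSe replicate 1 (1.549) and the mean correlation of MIX replicate 5 with the other arrays (0.9848) also stood apart.

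Each count of probes at an unadjusted p under 0.01 was set against 100 splits of the arrays into groups of the same sizes, the real one included. For any difference among ISe, OSe and MIX 1 split gave as many (1055, highest other 716), for OSe against MIX 1 (734, highest other 713), and for the midpoint 2 (637, highest other 735). These are fewer than 5 in 100, a bound set after the results were seen and not adjusted over the counts tested. In OSe against MIX the split with 713 exchanged MIX replicates 5, 6 and 7 with OSe replicates 2, 6 and 7. The real counts for OSe against MIX and the midpoint were both lower without MIX replicates 5, 6 and 7. The midpoint splits moved the labels of all 3 groups, so they cannot test the midpoint by itself. OSe against ISe also lay under the bound, with 2 splits (1132), and the highest other, 1148, was the split that exchanged ISe replicate 1 and OSe replicate 1. For MIX against ISe 5 splits gave as many (848), so this count did not lie under the bound and chance was not excluded. The highest other there called 1743, and 231 past the adjusted threshold. It set ISe replicates 2 to 6 with MIX replicates 2 and 3 against ISe replicate 1 with MIX replicates 1, 4, 5, 6 and 7. That is the real grouping with 3 arrays on the other side, so the arrays parted more clearly with these 3 moved than by their labels. For the number of called lists, 4 splits gave as many in OSe against ISe (8, highest other 10), just under the bound. That cannot exclude chance, since the splits are a sample and 0 list calls held with an estimated correlation. In MIX against ISe 26 splits gave as many (6, highest other 9) and in OSe against MIX 38 did (5, highest other 10), where chance was not excluded either.

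ISe replicate 1 lay nearer to the OSe arrays than to the other ISe arrays: on probes chosen without it, its position between the other ISe arrays (0) and OSe (1) was 0.778, where the other ISe arrays reached at most 0.502 and the OSe arrays began at 0.508. A wrong group label may account for this position, and the array lay as far toward MIX (0.794), but its posterior lobe score (0.633) was above every OSe array (at most 0.148) and its intermediate lobe score (-0.385) below every OSe array (lowest -0.312), so the label stays open. OSe had lower posterior lobe scores than ISe (-0.697), so more posterior lobe in this sample would not be expected to carry it toward OSe. The position was 0.753 once the trend with the posterior lobe score within groups was removed. For the same reason that step could not test more posterior lobe as the cause. Variation between steers was not tested, and 7 of the 20 arrays were nearer to another group than to their own. These were ISe replicate 1, OSe replicates 1 and 2, and MIX replicates 1, 2, 3 and 4. Of the MIX arrays only replicates 5, 6 and 7 were nearest to MIX.

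Intermediate lobe genes, among them POMC, DRD2 and PCSK2, were higher in OSe than in ISe. A larger piece of the attached posterior and intermediate lobes together in the OSe samples is argued against by the posterior lobe score, which differed by -0.697. This has limits: the exact permutation p of that score was 0.0524 adjusted over the 90 such tests, the lowest that a single list could reach by itself. Among probes above the median probe the posterior lobe list did not pass (camera adjusted p = 0.359). Less posterior lobe would raise all endocrine types alike. The intermediate lobe score exceeded the mean of the somatotroph, gonadotroph and thyrotroph scores by 0.726 more in OSe than in ISe (exact permutation p = 0.0315, not adjusted). This cannot exclude less posterior lobe, because the intermediate lobe list was examined for having risen. GH1, LHB and CGA in the other lists also lie near the top of the scale, where differences are compressed. A larger share of intermediate lobe cells could explain the pattern. With the score of the other intermediate lobe genes as a covariate POMC differed by 0.0549 ± 0.118 in place of 0.299 ± 0.106, which a change of the same genes within cells would give too, so share and regulation by selenium form cannot be told apart. A grouping of the arrays by chance stays open as well. The exact permutation p of the intermediate lobe score was 0.0524 adjusted over the 90 such tests. A single list could go no lower by itself, so this test could not exclude chance. Camera gave adjusted p = 0.467 with an estimated correlation.

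ER stress genes, among them HERPUD1, XBP1 and DDIT3, were higher in MIX than in ISe. A single array as the cause is argued against by the fits that left out each array, in which camera's adjusted p was at most 4.15e-08, and by an exact permutation p of 0.00216 for the score without MIX replicate 5. A grouping of the arrays by chance stays open: the list was picked as the strongest in camera, although fry's adjusted p was 0.0228. The exact permutation p of its score was 0.0524 adjusted over the 90 such tests. A single list could go no lower by itself, so that test could not exclude chance. An effect of the blend, or an unrecorded difference in handling or batch between the groups, might each account for it too, and neither was tested.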

How the results depend on the processing

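The fits without the 2 arrays of lowest weight (ISe replicate 6 and MIX replicate 5) and without MIX replicates 5, 6 and 7 were chosen only after the results were seen. So was the rule that a change of sign counts as a reversal only if 1 of the 2 fits has an unadjusted p under 0.05. Of 10429 values under alternatives 10052 kept their side of the threshold or, for counts and the correlation, moved little, and these include the changes of sign given next. Of 6621 gene values 102 changed sign, all with unadjusted p of 0.05 or more, and 178 passed the adjusted threshold, which no gene did as reported. Of 663 values of called lists 608 stayed past the threshold. Of 3138 list values, 95 changed direction and 22 passed among lists not called. A single value reversed. The OSe against ISe calls of ER stress, oxidative phosphorylation, ribosomal, glucocorticoid-responsive, immune and intermediate lobe genes stayed past the threshold under every alternative with the preset correlation, at most 0.0417, and the ER stress call in MIX against ISe at most 2.51e-05.

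With the inter-gene correlation estimated from the data 0 lists were called in OSe against ISe, 0 in MIX against ISe and 0 in OSe against MIX. In OSe against ISe the adjusted p was then 0.467 for the intermediate lobe and posterior lobe, 0.487 for oxidative phosphorylation, ER stress, prohormone processing and glucocorticoid-responsive genes, 0.524 for immune cells and 0.635 for ribosomal proteins. In MIX against ISe it was 0.467 for ER stress, 0.487 for oxidative phosphorylation, the proteasome and selenoproteins, 0.543 for heat shock proteins and 0.635 for immune cells. In OSe against MIX it was 0.487 for the proteasome, heat shock proteins and prohormone processing, 0.524 for glucocorticoid-responsive genes and 0.769 for ribosomal proteins. Only this setting differed from the main camera run. Its estimate was 0.54 for glucocorticoid-responsive genes, 0.41 for ribosomal proteins, 0.31 for immune cells and 0.25 for ER stress and heat shock proteins. It was 0.24 for the proteasome, 0.17 for oxidative phosphorylation, 0.11 for prohormone processing and 0.05 to 0.10 for the other called lists. The preset was 0.01. For ER stress in MIX against ISe camera's unadjusted p was 1.32e-11 with the preset and 0.0087 with the estimate.

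Quantile normalization gave 11 probes for OSe against ISe, 0 hormone genes in OSe against ISe, 0 selenoproteins in MIX against ISe, and 0.0525 for heat shock proteins in MIX against ISe. With only probes above the median probe, which tests fewer probes, OSe against ISe gave 105 probes and 6 selenoproteins, the counts at an unadjusted p under 0.01 were 481 for OSe against MIX and 369 for the midpoint, and the correlation of the 2 comparisons with ISe was 0.684. The lists were then at 0.359 (posterior lobe, OSe against ISe), 0.0734 (immune cells, MIX against ISe) and 0.115 (heat shock proteins, MIX against ISe). With only probes of 1 gene symbol there were 38 probes and 2 selenoproteins for OSe against ISe. Without variance moderation there was 1 probe for OSe against MIX and 1 hormone gene for OSe against ISe. A trended and robust eBayes gave 53 probes for OSe against ISe. Array weights gave 32 probes and 2 selenoproteins for OSe against ISe, 0 selenoproteins for MIX against ISe, and 0.103 for immune cells and 0.0838 for heat shock proteins in MIX against ISe. Fits on only the 2 groups compared, which hold fewer arrays, gave 2 selenoproteins in OSe against ISe and 0 in MIX against ISe. For the other changes the cause was not tested. At an unadjusted p under 0.01 as the threshold the counts were 1055 (any difference), 1132 (OSe against ISe), 848 (MIX against ISe) and 734 (OSe against MIX).

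The replicate numbers did not pair the arrays. Of 19 pairs with the same number 1 correlated above 0.1 once group means were removed, the range was -0.123 to 0.134, and 2 of 20 arrays correlated best with an array of their own number. A block on the number gave 0, 0 and 0 selenoproteins in OSe against ISe, MIX against ISe and OSe against MIX, and 0.0547 for heat shock proteins in MIX against ISe.

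With the posterior lobe score as a covariate, which takes part of the group difference with it, the counts at an unadjusted p under 0.01 were 653 (any difference), 584 (OSe against ISe) and 490 (MIX against ISe). There were 9 probes past the adjusted threshold, 0 hormone genes and 0 selenoproteins in OSe against ISe, 0 selenoproteins in MIX against ISe, and heat shock proteins were at 0.458 in MIX against ISe. With the intermediate lobe score the counts at an unadjusted p under 0.01 were 606 (any difference) and 475 (OSe against ISe). MIX against ISe gave 2 probes, hormone genes 0 in OSe against ISe, and selenoproteins 0, 0 and 0 in the 3 contrasts. Prohormone processing was at 0.365 in OSe against ISe and 0.209 in OSe against MIX, and the correlation of the 2 comparisons with ISe was 0.68. With the ISe arrays split 3 and 3 that correlation was 0.141.

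Without the 2 arrays of lowest weight 1 probe passed for any difference, 1 for MIX against ISe and 1 for the midpoint, and the counts at an unadjusted p under 0.01 were 675 (any difference) and 461 (MIX against ISe). Hormone genes were 0 in OSe against ISe, selenoproteins 0, 0 and 0 in the 3 contrasts, and in MIX against ISe immune cells were at 0.164 and heat shock proteins at 0.203. Without MIX replicates 5, 6 and 7, 2 probes passed for any difference, 4 for OSe against ISe (ZDBF2, BHLHE40, MIR1301 and CFAP43, named after their values were seen) and 1 for MIX against ISe. The counts at an unadjusted p under 0.01 were 236 (MIX against ISe), 417 (OSe against MIX) and 225 (midpoint), and selenoproteins were 2, 0 and 0 in the 3 contrasts. Chance gives 268 probes, so 236 and 225 were no excess. In MIX against ISe the adjusted p was 0.273 for selenoproteins, 0.126 for oxidative phosphorylation, 0.126 for the proteasome and 0.76 for heat shock proteins. In OSe against MIX it was 0.511 for the proteasome, 0.166 for glucocorticoid-responsive genes and 0.312 for heat shock proteins, and ER stress genes reversed from lower to higher in OSe, at 0.777. These fits hold fewer arrays.

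Lists not called as reported passed as follows. Without MIX replicates 5, 6 and 7, glucocorticoid-responsive genes (0.00174) and fibroblasts and mural cells (0.00947) passed as lower in MIX than ISe. With the same arrays left out, the exact permutation p of these scores was 0.238 and 0.267. In OSe against MIX, oxidative phosphorylation (0.00226) and cholesterol synthesis (0.0489) passed without MIX replicates 5, 6 and 7. Glucocorticoid-responsive genes in MIX against ISe also passed with the posterior lobe score (0.0147), without ISe replicate 2 (0.0395) and without the 2 arrays of lowest weight (0.0446). In MIX against ISe fibroblasts and mural cells passed without ISe replicate 1 (0.0379) or MIX replicate 5 (just under 0.05), ribosomal proteins without ISe replicate 1 (0.0124), blood without ISe replicate 3 (0.018) and the posterior lobe without MIX replicate 4 (0.0377). The intermediate lobe passed in OSe against MIX with only probes above the median probe (0.0162), and heat shock proteins in OSe against ISe with the posterior lobe score (0.0369). ER stress in OSe against MIX passed in 8 fits, at 0.00958 to 0.0481. The causes were not tested.

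Leaving out each array in turn gave the following lowest and highest values where any fit changed. Probes past the adjusted threshold were 0 to 6 for any difference, 0 to 241 for OSe against ISe, 0 to 1 for MIX against ISe and 0 to 1 for the midpoint. At an unadjusted p under 0.01 they were 748 to 1678 for OSe against ISe, 531 to 1324 for MIX against ISe and 377 to 787 for the midpoint. Hormone genes were 0 to 3 in OSe against ISe and 0 to 1 in MIX against ISe, and selenoproteins 0 to 6 and 0 to 6. Adjusted p was 0.00578 to 0.0976 for heat shock proteins and 0.0040 to 0.114 for immune cells in MIX against ISe, and 1.37e-04 to 0.0599 for ribosomal proteins and 0.00294 to 0.114 for prohormone processing in OSe against MIX. The correlation of the 2 comparisons with ISe was 0.537 to 0.655. At an unadjusted p under 0.01 the highest count for OSe against ISe came without ISe replicate 1 and the lowest for MIX against ISe without MIX replicate 5. Background signal was not used here, so what it limits was not measured, and brightness near the top of the scale limits GH1, LHB, CGA, PRL and POMC.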

Other observations

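The lists of motile cilia genes, ATF4 targets and hypoxia targets were written after the ranked genes had been seen and before their own scores were. DNAI3 and CFAP43, genes of the ciliary axoneme, were lower in OSe than in ISe, and fewer or less active ciliated cells may be a cause. The motile cilia score differed by -0.216 between OSe and ISe (exact permutation p = 0.27, camera's unadjusted p with the preset correlation 0.182, 12 of 20 members below 0) and by -0.489 between MIX and ISe (p = 0.0938, camera 0.00189, 17 of 20 below 0). ASNS was higher in OSe and MIX than in ISe, which a wider ATF4 response could give. The ATF4 target score differed by 0.263 in OSe (exact permutation p = 0.188, camera 0.157) and 0.445 in MIX (p = 0.067, camera 0.0115). BHLHE40 was higher in both groups too, which a hypoxia response could give, and the hypoxia score differed by 0.143 in OSe (exact permutation p = 0.356, camera 0.385) and 0.294 in MIX (p = 0.107, camera 0.104). The bound set beforehand, that a p of 0.05 or more would argue against each of these, was wrong, because missing a threshold with 6 and 7 arrays excludes nothing, and all 3 stay open.

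MIX replicates 5, 6 and 7 lay apart from the other MIX arrays in several scores. Their oxidative phosphorylation scores were 0.777, 0.475 and 0.602, and those of the other MIX arrays lay between -0.339 and 0.119. Batch and handling records are not given in the sources used here. OXT, the oxytocin gene and a member of the posterior lobe list, was 6.75 in ISe replicate 1 and at most 4.66 in the other arrays.

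In exact permutation tests of the list scores, chosen after the data had been seen, the smallest p of 90 was 5.83e-04 for clock genes in MIX against ISe (difference in score 0.295). It was 0.00175 for ER stress (0.729) and for posterior lobe genes (-0.697) in OSe against ISe, 0.00291 for intermediate lobe genes (0.886) and 0.00524 for prohormone processing (0.664). Adjusted over the 90 tests the smallest was 0.0524. With 1716 permutations 5.83e-04 is the smallest p the test can give, so a single list could not have passed this adjustment by itself.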
